A study of Mus musculus with 6 samples.

How the data were processed

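Gene expression was measured by RNA-seq in 6 libraries labelled as mouse kidney tissue on day 2, 3 from I/R and 3 from I/R with chemerin-9. Per the labels' protocols, total RNA was extracted with a Qiagen reagent and libraries were made with a Vazyme stranded mRNA kit. The submitters' processing notes name HISAT2 for alignment, HTSeq for counting, DESeq 1.18.1 and the genome build mm10. The annotation release and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes are uncertain.

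The deposited table held raw counts per gene symbol for the 6 libraries, made by the authors with no normalization according to the values, which are whole numbers with different totals. The same table held the authors' log2 fold change, fold change ratio, p-value and FDR per gene, as deposited by the authors. DESeq is named in the processing notes, but which settings made these columns is not given in the sources used here. The coordinates in the table matched GRCm38, since 97.5% of the genes found in GENCODE M21 had the same start. The table had 25216 rows, of which 27 repeated the symbol and counts of another row and were removed, leaving 25189 symbols, 622 of them with no count in any library. No row stood for unassigned reads. Genes without a row were not analysed here.

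Groups were taken from the sample titles. The treatment field of the treated samples reads C9, C10 and C11 in turn, while all 3 titles read C9, and the titles were followed. The table names the treated columns IC with a number. The labels of the treated samples instead name columns with the letter S, of another table, and IC was read as the initials of I/R and C9. That reading could not be checked against a name in the labels. The labels do name the I columns for I/R. What rests on the reading is which group the IC columns are, and with it every statement on chemerin-9. Replicate numbers are those of the titles. Each library has its own batch value, so batch could not be a term in the model. These values are 6 consecutive dates and could, like the treatment field, come from filling down a column.

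Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM size factors, the filterByExpr filter by group, a quasi-likelihood fit on group alone, and Benjamini-Hochberg adjustment over the 14184 genes tested at a threshold of 0.05. Values in CPM are counts scaled by the TMM-adjusted library size, given as mean ± SD over 3 libraries. The biological coefficient of variation was 5.18%, at 6.51% within I/R and 3.32% within I/R with chemerin-9. The tested genes held 99.8% of the counts, and a gene at the median level had 295 counts in the shallowest library. The 40 gene lists were tested two-sided against all other tested genes with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01, where at least 3 members were tested. Benjamini-Hochberg adjustment ran over the 35 lists tested. Principal components were computed from the 500 most variable genes.

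The gene lists, the tests, the rule for named genes and the alternatives, apart from those said below to be added, were chosen before the data were examined. The rule for named genes took the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05, a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted-gene name. It added the 16 genes of the title set and up to 4 members with the smallest p of each list described. Copies of the named genes were searched among GENCODE M21 transcripts with BLAST 2.17.0 at 95% identity over at least 50% of the shorter transcript. Of 163 genes searched, 40 had such a copy. Copies are pointed out below for only some of these genes. Fdps, Ldha, Pkm, Me1, Fth1 and Acsf2 are among the others with a copy.

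The alternatives were other size factors (RLE and upper quartile), DESeq2 1.42.0, limma-voom, a robust prior, other filters on low counts, the replicate number as a block, each library left out in turn, a threshold of 0.1, and mitochondrial and haemoglobin genes left out. For lists they were an estimated correlation, fry and a rank-based camera. A fit with the trend on GC content and transcript length removed was added after the data were seen, for the 96.2% of tested genes with a matched transcript, as were the alternatives for the principal components.

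The procedures were tested on simulated data drawn from the means and library sizes of this comparison. With 13955 genes tested and known changes, edgeR recovered 46.8% of genes changed 1.25-fold, 68.0% of those changed 1.5-fold, 87.5% of those changed 2-fold and all 48 of those changed 3-fold, and 8.18% of its calls were false. Only 47 to 50 genes were changed at each fold, whereas 51.7% of the tested genes were called in the real data. These rates depend on that share and may not carry over to the real calls. For lists, on 13923 genes, camera with the preset correlation recovered 8 of 10 lists shifted by 0.3 on the log2 scale and called none of 30 others, while with an estimated correlation it recovered none and fry recovered 10. The simulated genes varied independently, whereas the estimated correlation reached 0.658 in the real ribosomal protein list. The simulation therefore cannot show how often the preset correlation calls correlated lists falsely. With a simulated GC trend between the groups, the fit without a correction made 6240 false calls among 13936 genes, and the fit with the trend removed made 14 among 13424.

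By the FDR that the authors deposited, 6012 genes were under 0.05, 3000 higher and 3012 lower. Of the genes tested here, 5909 were called in the authors' deposited table, 5907 of them also here and all 5907 in the same direction.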

Results

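RNA was sequenced from samples labelled as kidney tissue of male wild-type C57BL/6 mice on day 2 after ischaemia and reperfusion (I/R), an injury made by stopping and then restoring the blood flow of the kidney. One group of 3 libraries came from I/R alone and the other group of 3 came from I/R with chemerin-9, a short peptide from the carboxyl end of chemerin that activates the chemerin receptor. The study's title names ferroptosis, a form of cell death driven by iron and lipid peroxidation, and an axis of AMPK, NRF2 and the cystine transporter SLC7A11. The comparison asks what chemerin-9 changed in the injured kidney and whether the genes of that axis were among the changes. The libraries held 13069464, 13817752 and 16938301 counts in I/R and 11217252, 13274436 and 14004529 counts in I/R with chemerin-9, over 20611 to 21171 genes with at least 1 count. The labels do not say that each library came from its own mouse, so the p-values measure the spread between these libraries, which may be technical. No library duplicated another, because every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom between 1.82 and 6.25. The I/R replicate 3 library stood apart from the other I/R libraries, at 6.25 and 5.70 against 1.82 between those.

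The genes that mark kidney cell types were near the floor in all 6 libraries, and genes of dividing and matrix-producing cells were abundant. Over the 41 nephron marker genes with a row in the table, the median level in a library lay between 1.40 and 2.14 CPM (counts scaled to the library size), against 25.7 to 26.3 CPM for all tested genes. Over 44 marker genes of blood vessels, leukocytes and red blood cells it lay between 0.334 and 0.663 CPM. Lrp2, the endocytic receptor of the proximal tubule, held 3.19 ± 0.531 CPM in I/R and 3.37 ± 0.747 CPM with chemerin-9 (SD, n = 3 each). Slc12a1, the salt transporter of the loop of Henle, held 0.753 ± 0.0986 and 0.515 ± 0.321 CPM. Aqp2, the water channel of the collecting duct, held 0.0926 ± 0.0821 and 0.107 ± 0.0938 CPM. Pecam1 of endothelium was at 0.119 ± 0.117 and 0.478 ± 0.224 CPM. The macrophage gene Lyz2 was at 1.72 ± 0.616 and 1.74 ± 0.152 CPM, and the injury marker Lcn2 at 1.20 ± 0.246 and 1.45 ± 0.479 CPM. By contrast, the 42 cell division genes had a median of 209 to 221 CPM per library. Among them Top2a was at 1752 ± 46.8 and 1757 ± 45.4 CPM and Mki67 at 1050 ± 22.4 and 938 ± 14.4 CPM. The collagen gene Col1a1 reached 771 ± 28.2 and 800 ± 20.5 CPM. Unlike Lcn2, the tubular injury list as a whole was not near the floor. Its 26 genes with a row had a median of 59.5 to 74.2 CPM per library. The genes of this paragraph were chosen after their values were seen, and many other kidney markers, among them Umod and Havcr1, were not analysed here.

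**Figure D1:**
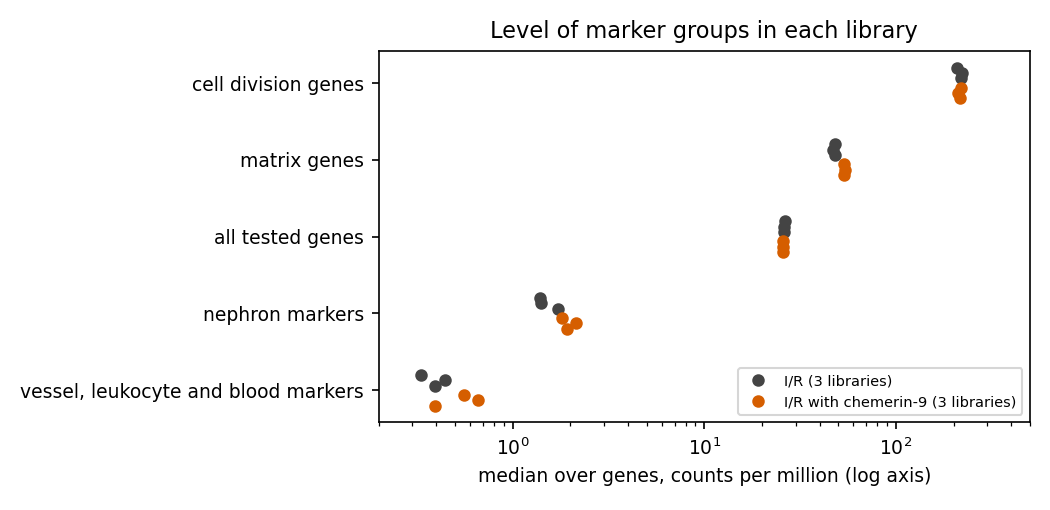
Median level of 5 gene groups in each library, in CPM on a log axis, with 1 point per library (grey, I/R; orange, I/R with chemerin-9; 3 libraries each). In all 6 libraries the nephron markers (1.40 to 2.14) and the vessel, leukocyte and blood markers (0.334 to 0.663) lie below the median of all tested genes, and the cell division genes (209 to 221) lie above it.

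Chemerin-9 went with a broad fall of interferon-induced, chaperone and cholesterol synthesis genes and a rise of Igf1 and several weakly expressed genes. Of the 31 tested interferon response genes, 30 fell and none rose. Mx2 fell from 8.10 ± 0.835 to 0.698 ± 0.159 CPM, and Isg15, a ubiquitin-like interferon product, fell from 78.6 ± 8.21 to 14.1 ± 0.962 CPM (SD, n = 3 each). Hspb1, a small heat shock protein, fell from 202 ± 8.26 to 28.2 ± 2.89 CPM, and Igf1, the insulin-like growth factor, rose from 1.34 ± 0.275 to 11.3 ± 1.05 CPM. Across the 14184 genes tested with edgeR's quasi-likelihood test, 7336 changed at a Benjamini-Hochberg adjusted p under 0.05, 3637 higher and 3699 lower with chemerin-9. That is 51.7% of the tested genes, the share to set beside every count of changed list members below. In those counts, also under the alternatives, a gene is counted as risen or fallen only if its adjusted p was under 0.05. Most of these changes were small, and 5076 of them, or 69.2%, were under 1.5-fold. Of the changed genes, 847 reached 2-fold (491 higher and 356 lower) and 104 reached 4-fold. The 3 values of one group did not overlap those of the other in 58.5% of the tested genes, where chance gives 10%. On the main axis of variation, which carried 75.1% of the variance of the 500 most variable genes, the I/R libraries lay between -17.45 and -16.83 and the others between 16.16 and 18.34. The batch values in the labels are 6 consecutive dates, 1 per library and those of I/R first, and whether they are real processing days is uncertain. No value is shared by the groups, so an effect of batch and the treatment cannot be told apart. Libraries of the same group, which also differ in their batch value, had the chi-square values per degree of freedom given above, against 27.9 to 40.97 for pairs across the groups. The share of 18S RNA also separated the groups, at 0.381% to 0.517% of counts in I/R and 0.261% to 0.306% with chemerin-9. So did the mitochondrial share, at 2.81% to 2.94% and 2.56% to 2.64%.

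The 12 genes that rose most were mostly weakly expressed in I/R. Igf1 led with a log2 fold change of 3.09 (standard error 0.19, adjusted p = 6.6e-09, edgeR; chromosome 10, 87858265 to 87937042, GRCm38, ENSMUSG00000020053). It was followed by Ccn5 (2.47), a secreted matrix-associated protein, by Atp6v0a4 (2.46), a proton pump subunit, and by Gxylt2 (2.46), a xylosyltransferase acting on Notch-type repeats. The log2 fold change of Ccn5 was 3.06 without I/R replicate 3 and 2.24 without I/R replicate 2, so its rank among these is uncertain. Gxylt2 was the most abundant of the 12, rising from 5.99 ± 0.478 to 32.9 ± 1.33 CPM. Akap5, a kinase anchor, the mucin gene Muc2, Tincr, Sag, Dnhd1, the phospholipase gene Pla2g4c, the collagen gene Col20a1 and Adam1a also rose, by 1.89 to 2.25 on the log2 scale. Reads of Adam1a and Dnhd1 were uncertain, because each has a copy at over 95% identity over at least 50% of the shorter transcript.

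Of the 12 genes that fell most, 8 belong to the interferon response list. Mx2 (log2 fold change -3.54, standard error 0.23, adjusted p = 1.2e-08, edgeR; chromosome 16, GRCm38) was followed by Saa3 (-3.37), an acute phase serum amyloid, Rsad2 (-2.97), which encodes viperin, and Hspb1 (-2.84). Oasl2, Oas3 and Oas2 of the oligoadenylate synthetase family fell by 2.70, 2.60 and 2.38 on the log2 scale. Ifit1 and Ifit3 fell by 2.68 and 2.52, Isg15 by 2.48, the chemokine gene Cxcl10 by 2.41 and Phf11d by 2.28. All 12 kept an edgeR adjusted p under 0.05 without each library in turn. Mx2, Hspb1, Ifit3, Isg15 and Phf11d have a copy of at least 95% identity, so their counts may hold reads of the copy. Of these copies, Mx1 and Ifit3b had fitted log2 changes of -2.53 and -2.23.

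**Figure D2:**
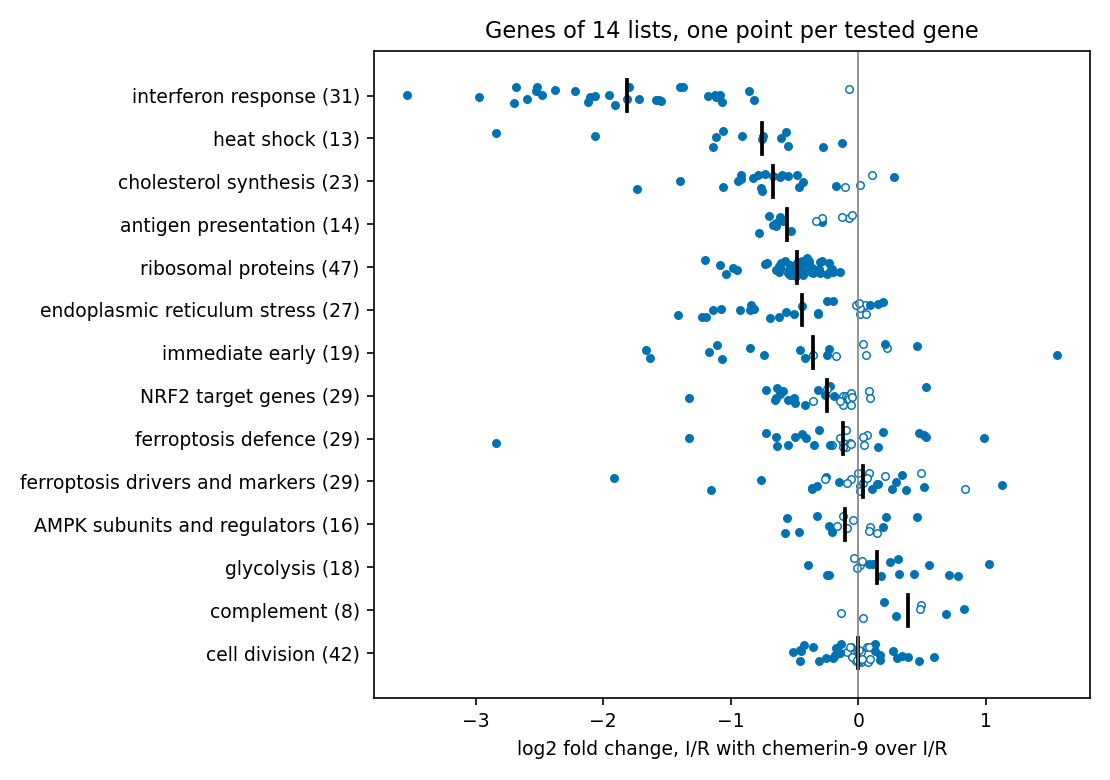
Log2 fold change of each tested gene of 14 lists, I/R with chemerin-9 over I/R, with the number of tested genes in parentheses, filled points for genes with an edgeR adjusted p under 0.05, open points for the others, and a black bar at the list's median. Medians run from -1.82 for interferon response genes to 0.39 for complement genes, and all heat shock and ribosomal protein genes lie below 0.

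Of 40 gene lists, 35 had at least 3 tested members. By limma's camera with a preset correlation of 0.01, 8 of these differed from the other genes, all 8 lower with chemerin-9. The interferon response list had a median log2 fold change of -1.82, and 30 of its 31 genes fell, also when adjusted over the list alone (camera adjusted p = 6.2e-18). Among them Ifi44 fell from 124 ± 5.76 to 35.003 ± 2.27 CPM, the signal transducer gene Stat2 from 107 ± 4.89 to 28.4 ± 2.03 CPM and Xaf1 by 2.22 on the log2 scale. In the antigen presentation list 9 of 14 genes fell and none rose, with 10 lower when adjusted over the list alone (median -0.56, camera adjusted p = 5.5e-04, or 0.698 with an estimated correlation). There B2m, the light chain of class I molecules, fell by 0.64 on the log2 scale, the class I gene H2-K1 by 0.53, and the peptide loading genes Tap1 and Tapbp by 0.78 and 0.70.

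All 13 tested heat shock genes fell, also when adjusted over the list alone, with a median log2 fold change of -0.75 (camera adjusted p = 2.1e-08). The number was 12 without I/R replicate 1, I/R replicate 2 or chemerin-9 replicate 3. Hspa8, the constitutive HSP70 chaperone, fell from 1948 ± 24.0 to 467 ± 8.38 CPM, and the HSP90 genes Hsp90ab1 and Hsp90aa1 fell by 1.14 and 1.06 on the log2 scale. The processed pseudogene Gm15459 (chromosome 5, 5781615 to 5783555, GRCm38), named after its values were seen, matches Hspa8 at 99.7% identity over all of its 1941 bp. Its log2 fold change was -2.07 against -2.06 for Hspa8, and reads of this pair could not be assigned with certainty. Of 15 heat shock genes searched, 8 have a copy of at least 95% identity, among them Hsp90aa1, so the counts of these members are uncertain. In the endoplasmic reticulum stress list 18 of 27 genes fell and 3 rose, the same numbers when adjusted over the list alone (median -0.45, camera adjusted p = 1.8e-05, or 0.054 with an estimated correlation). Its chaperones were among the most abundant genes that fell. Hspa5 fell from 2332 ± 26.5 to 1107 ± 11.2 CPM and Calr from 1215 ± 18.99 to 519 ± 6.88 CPM. Hsp90b1 and Pdia6 fell by 1.14 and 0.93 on the log2 scale. In the immediate early list 11 of 19 genes fell and 3 rose, the same numbers over the list alone (camera adjusted p = 0.038, or 0.703 with an estimated correlation). Ccn1, Nr4a1 and Klf6 fell by 1.67, 1.17 and 0.85 on the log2 scale, while Egr1 rose by 0.46.

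In cholesterol synthesis 19 of 23 genes fell and 1 rose, also when adjusted over the list alone (median -0.67, camera adjusted p = 2.1e-08), the rise being lost without I/R replicate 1 or chemerin-9 replicate 3. Insig1, a sterol-regulated brake on the pathway, fell from 187 ± 7.88 to 56.3 ± 5.12 CPM. Fdps fell by 0.92 on the log2 scale and Srebf2, the transcription factor of the pathway, by 0.73. All 47 tested ribosomal protein genes fell, over the list alone too, with a median log2 fold change of -0.48 (camera adjusted p = 2.7e-09, or 0.703 with an estimated correlation). With DESeq2 36 of the 47 passed as lower at an adjusted p under 0.05, and with a robust prior 28. The list's median level was 602 CPM in I/R replicate 3, against 442 and 463 CPM in the other I/R libraries, and the median log2 fold change was -0.38 without that library. Rplp0 fell from 2349 ± 73.9 to 1728 ± 32.5 CPM, Rpl4 by 0.46 on the log2 scale and Rpl7 and Rps24 by 0.52 each. Of the 48 genes of that list, 46 have a copy of at least 95% identity, so the counts of single members are uncertain.

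With a correlation estimated for each list, 3 of the 8 list calls held: interferon response, cholesterol synthesis and heat shock each had an adjusted p of 0.037. The other 5 calls did not hold. In the simulated data this setting recovered 0 of 10 shifted lists, so a lost call does not show that a list was unchanged. For endoplasmic reticulum stress and NRF2 target genes the estimated correlation (-0.024 and 0.0070) was below the preset 0.01, and the call was still lost. Another split of the same libraries into 3 and 3 gave 11 lists with the preset correlation, more than the real 8. The number of lists alone therefore does not set the real grouping apart. Every other split mixes the groups unequally, so it keeps part of the group difference and does not show what arises without one. The immediate early call also ended with the replicate number as a block (adjusted p = 0.053), by rank-based camera (0.059) and with the GC and length trend removed (0.124). It ended without I/R replicate 3 (adjusted p = 0.083) and without chemerin-9 replicate 3 (adjusted p = 0.074) too, over a range of 0.0019 to 0.70 across its alternatives.

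For the genes of the study's title, the cystine transporter rose and the lipid peroxide reductase fell. Slc7a11, the cystine import subunit, rose from 161 ± 1.89 to 232 ± 4.62 CPM (log2 fold change 0.53, standard error 0.04, adjusted p = 1.6e-08, edgeR; chromosome 3, 49892526 to 50443614, GRCm38, ENSMUSG00000027737). Its partner chain Slc3a2 rose from 411 ± 6.58 to 470 ± 16.2 CPM. Gpx4, the enzyme that reduces lipid peroxides and so opposes ferroptosis, fell from 251 ± 24.998 to 185 ± 3.05 CPM (log2 fold change -0.44, adjusted p = 9.9e-06, edgeR; chromosome 10, 80047166 to 80056439). Acsl4, which supplies the lipids that are peroxidised, fell from 271 ± 3.70 to 243 ± 4.02 CPM, and Ptgs2, often read as a ferroptosis marker, fell from 70.9 ± 1.92 to 56.7 ± 3.48 CPM.

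Nfe2l2, which encodes NRF2, went from 38.4 ± 0.981 to 42.8 ± 0.939 CPM (log2 fold change 0.16, adjusted p = 0.039, edgeR). Its inhibitor Keap1 did not pass (log2 fold change -0.051, adjusted p = 0.70, edgeR). The AMPK catalytic gene Prkaa1 rose from 235 ± 8.22 to 272 ± 4.92 CPM. The regulatory subunit genes Prkab2 and Prkag1 fell, from 47.2 ± 3.06 to 31.6 ± 0.909 CPM and from 13.2 ± 1.58 to 8.97 ± 1.26 CPM, while Prkab1 and Prkag2 did not pass (adjusted p = 0.32 for each, edgeR). In all, 9 of the 12 tested genes of this set of 16 changed, 4 higher and 5 lower, and 9 changed when adjusted over the list alone. Among all tested genes 51.7% changed, so this count does not by itself set these genes apart. These values are RNA levels, and the activity of AMPK and NRF2 was not measured here. Ccrl2, a chemerin-binding receptor, stayed under the count filter at 0.484 ± 0.164 and 0.151 ± 0.141 CPM, and Prkaa2, Cmklr1 and Rarres2 were not analysed here. The Nfe2l2 call was lost with DESeq2 (adjusted p = 0.12), with the replicate block (0.059), with no filter on low counts (0.103), with the GC and length trend removed (0.104) and without any 1 of the 6 libraries (adjusted p = 0.062 to 0.12), over a range of 0.026 to 0.12 across its alternatives. With the GC and length trend removed, the log2 fold change of Prkaa1 went from 0.22 to 0.094, that of Gpx4 from -0.44 to -0.26, that of Acsl4 from -0.16 to -0.30 and that of Slc7a11 from 0.53 to 0.36, each with an adjusted p under 0.05. Gpx4 has copies at over 95% identity, and the closest, Gpx4-ps2, had a fitted log2 fold change of -0.34.

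**Figure D3:**
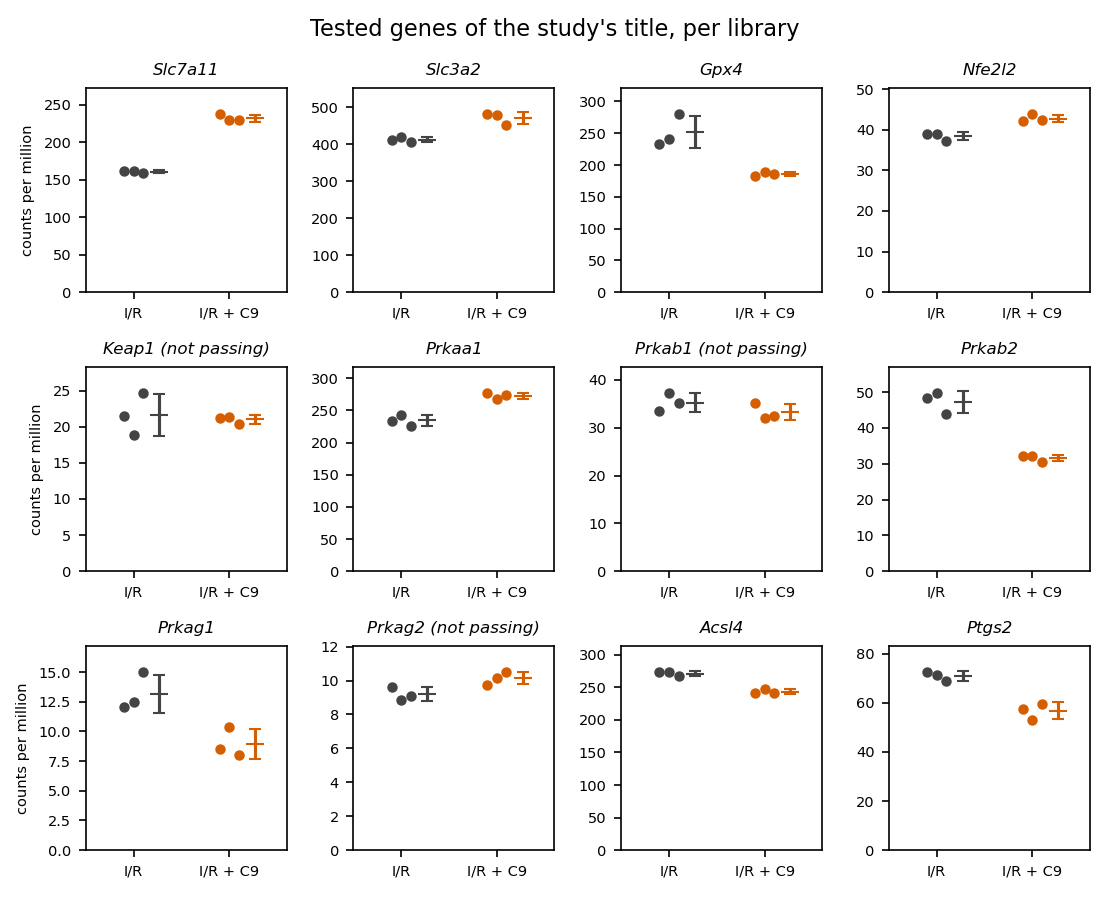
Level of the 12 tested genes of the study's title in each library, in CPM on axes that start at 0, with 1 point per library and the group's mean and SD beside the points (3 libraries per group). Slc7a11 lies at 161 in I/R and 232 with chemerin-9, Gpx4 at 251 and 185, and the genes marked as not passing had an edgeR adjusted p above 0.05.

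Of the wider lists behind the title, 1 passed as a list. Of 29 NRF2 target genes, 15 fell and 1 rose, the same numbers when adjusted over the list alone (median -0.25, camera adjusted p = 4.0e-04, or 0.103 with an estimated correlation). Among them the ferritin heavy chain gene Fth1 fell from 526 ± 39.9 to 318 ± 14.4 CPM, Me1, which makes NADPH, by 0.66 on the log2 scale and the exporter gene Abcc1 by 0.50. The gene that rose was Slc7a11. Of 29 ferroptosis defence genes, 6 rose and 12 fell, also over the list alone, and the list as a whole did not pass (camera adjusted p = 0.074). It passed, lower with chemerin-9, with no filter on low counts (adjusted p = 0.022), with the GC and length trend removed (0.049) and by fry, over a range of 3.2e-04 to 0.38 across its alternatives. Hspb1, Fth1 and the iron chaperone gene Pcbp1 (-0.64) were among those that fell. Of 29 ferroptosis drivers and markers, 9 rose and 8 fell, also over the list alone, and the list did not pass (camera adjusted p = 0.99). Its median lay above 0 (0.039) and its mean below (-0.021). Tfrc, the transferrin receptor that brings iron into cells, fell from 275 ± 9.16 to 73.0 ± 1.91 CPM. Acsf2 fell by 1.16 on the log2 scale and the polyamine enzyme gene Sat1 by 0.77, while the metal transporter gene Slc39a14 rose by 0.38. Of 16 AMPK subunits and regulators, 3 rose and 6 fell (7 lower when adjusted over the list alone; camera adjusted p = 0.57). The AMPK kinase gene Stk11 fell by 0.47 on the log2 scale and Sesn3 rose by 0.46. Of 16 iron handling genes, 5 rose and 5 fell, the same over the list alone (camera adjusted p = 0.70). The haem transporter gene Slc48a1 fell by 0.68 on the log2 scale.

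Glycolysis genes were mostly higher, as 11 of 18 rose and 3 fell, also when adjusted over the list alone. The list as a whole did not pass (median 0.15, camera adjusted p = 0.060), but it passed without I/R replicate 3 (adjusted p = 0.049). It also passed with no filter on low counts (0.040), with the GC and length trend removed (0.0081) and by fry, over a range of 8.7e-04 to 0.70 across its alternatives. Ldha, the lactate dehydrogenase gene, rose from 772 ± 16.5 to 1329 ± 13.8 CPM. Pdk1, a pyruvate dehydrogenase kinase gene, rose by 1.03 on the log2 scale, Pfkl by 0.71 and Pkm by 0.44. Of 42 cell division genes, 10 rose and 14 fell (camera adjusted p = 0.70). Rrm2 and Mcm5 of DNA replication rose by 0.48 and 0.34, and Kif20a and Cdc20 of mitosis fell by 0.45 and 0.51. Of 44 nuclear genes of mitochondrial respiration, 8 rose and 18 fell, with 19 lower over the list alone (camera adjusted p = 0.55). Sdha rose by 0.51 and Atp5a1 fell by 0.34. Of 14 mitochondrial genome genes, 2 rose and 5 fell (camera adjusted p = 0.55), and mt-Co1, the most abundant gene of every library, fell by 0.39. Fatty acid oxidation held 6 higher and 6 lower genes of 25 (camera adjusted p = 0.97), with Decr1 higher by 0.76 and Acaa1a lower by 0.71. Over the list alone the numbers for cell division, the mitochondrial genome and fatty acid oxidation were the same.

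Among tubular injury genes 6 of 22 rose and 8 fell, with 7 and 9 over the list alone (camera adjusted p = 0.77). The adhesion gene Vcam1 rose by 0.81 on the log2 scale and Anxa2 by 0.26, and Cryab and Vim fell by 1.46 and 0.68. Among matrix genes 8 of 24 rose and 11 fell, with 9 and 12 over the list alone (camera adjusted p = 0.70). Fbn1 and Loxl2 rose by 0.92 and 0.89, and Ccn2 and Tnc fell by 1.83 and 0.66. Of 18 cytokine and chemokine genes 10 rose and 3 fell, also over the list alone (camera adjusted p = 0.38). Csf1 rose by 0.36, Ccl2 by 0.86 and Nfkb2 by 0.25, and Cxcl10 fell. Of 8 complement genes 4 rose and none fell, also over the list alone (camera adjusted p = 0.074), and the list passed without I/R replicate 1 (adjusted p = 0.047), with the GC and length trend removed (0.049) and by fry, over a range of 0.0087 to 0.38 across its alternatives. Only 2 of these genes rose without I/R replicate 2 or chemerin-9 replicate 3. Masp1 and C1s1 rose by 0.83 and 0.69. Of 28 genes of the p53 response and apoptosis 7 rose and 10 fell, also over the list alone (camera adjusted p = 0.70). Aen and Bcl2l1 rose by 0.75 and 0.52, and Bbc3 and Trp53inp1 fell by 1.14 and 0.64. Of 11 necroptosis and pyroptosis genes 2 rose and 2 fell, with 1 and 2 over the list alone (camera adjusted p = 0.99). Only 1 rose without any 1 of the libraries other than chemerin-9 replicate 3. Their median (-0.065) and mean (-0.12) lay below 0 while camera's direction was up. Gsdme rose by 0.42 and Zbp1 fell by 1.37.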

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

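The alternatives with the GC and length trend removed and those for the principal components were chosen after the data were seen. The number of changed genes (7336) stayed within 1.5 times under every alternative run, from 6312 with DESeq2 to 7747 with no filter on low counts and 8338 at a threshold of 0.1, and without each library in turn it ran from 6399 to 7323. With the GC and length trend removed 7155 were called, 6224 of them among the 7336. Of the 7336 genes, 5525 (75.3%) were called without each library in turn. No scaling moved the median of all genes by over 0.1 on the log2 scale. Each scaling centres the bulk of the genes, so this could hardly come out otherwise. It does not test whether most genes were unchanged. The number at least 2-fold higher went from 491 to 763 with no filter, which tests more weakly expressed genes. The number of lists changed (8) was 3 with an estimated correlation and 20 with fry, which does not compare a list with other genes. The list of ferroptosis drivers and markers, not passing by camera, was lower by fry (adjusted p = 0.00501), and the cause was not tested. The share of the main axis (75.1%) was 62.4% with no filter, which lets weakly expressed genes in, and 72.4% to 74.7% without each library in turn. Of the other results, 426 values for single lists kept their call, 10 lost and 18 gained it, and 1914 values for named genes kept their call, 44 lost and 9 gained it. Replicate numbers did not pair the libraries (correlations of deviations 0.102, -0.052 and 0.042 for equal numbers), and with the replicate block 7300 genes, 846 at 2-fold, 7 lists and 8 title genes were called. The alternatives meant for normalized values were not run, since the table holds counts. Depth limits what can be said of weakly expressed genes, such as most kidney markers.

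The labels of 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7336 genes and 847 at 2-fold, each in 1 of the 10 splits. The highest other split gave 0 for both. Every other split mixes the groups, which widens the spread within its sides, so a low number could hardly come out otherwise. For lists, 4 of the 10 splits gave as many as the real 8, and the highest other gave 11. The mixing is unequal, so these splits keep part of the group difference and do not show what arises without one.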

Other observations

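The KEGG pathway test and the tests of explanations on marker levels, depth, abundant genes and batch values were chosen only after the result was seen, while those on GC content and length were set after the data but before their own result was seen. Other cell type and tissue lists had few tested members and none passed camera at the preset correlation. Of 8 podocyte genes 4 rose and 1 fell, the same over the list alone (adjusted p = 0.55): Magi2 and Synpo rose by 1.42 and 0.95 on the log2 scale and Nes fell by 0.43. Of 9 proximal tubule genes 1 rose and 2 fell, with 1 and 1 adjusted over the list alone (adjusted p = 0.97). Their median (0.042) and mean (0.034) lay above 0 while camera's direction was down. The fall of Ggt1 (-1.01) was lost with DESeq2, with the GC and length trend removed, and without I/R replicate 1 or 2 or chemerin-9 replicate 1 or 3, over adjusted p values of 0.011 to 0.151. Of 3 collecting duct genes 2 rose (Fxyd4 by 1.01 and Gata3 by 0.70; list adjusted p = 0.47), where the Gata3 call was lost without chemerin-9 replicate 2 (edgeR adjusted p = 0.058, range 0.0057 to 0.058). Of 4 endothelial genes 2 rose (Flt1 by 0.93 and Plat by 0.56; list adjusted p = 0.38). None of the 3 distal tubule genes (adjusted p = 0.47) or 3 erythrocyte genes (adjusted p = 0.70) passed, and the 2 loop of Henle, 2 neutrophil and 1 B cell genes that could be tested did not pass either. Without chemerin-9 replicate 3 there was 1 distal tubule gene that rose, and without I/R replicate 2 or 3 there was 1 erythrocyte gene. Of 6 macrophage genes, a list with a camera adjusted p of 0.85, 1 fell. This was Aif1 (edgeR adjusted p = 0.012), a call lost without chemerin-9 replicate 1 or 2 (adjusted p = 0.058 and 0.061, range 7.6e-04 to 0.061), while 2 of 7 fell without I/R replicate 1. Of 3 T and NK cell genes 1 fell (Ccl5, by 1.45; list adjusted p = 0.57), and of 4 muscle genes 1 fell (Acta1, by 1.62; list adjusted p = 0.70), or 2 of 5 without I/R replicate 3. Of 3 adrenal genes 1 rose (Star, by 1.13) and 1 fell (Fdx1; list adjusted p = 0.92), a call lost without chemerin-9 replicate 1 (edgeR adjusted p = 0.067, range 0.0056 to 0.067). The adrenal list had a median of -0.37 and a mean of 0.11, with camera's direction down. None of the 6 fat tissue genes with a row was high enough to test, nor was Ccrl2, the 1 gene with a row of the list of chemerin and its receptors, and the other genes of these lists were not analysed here.

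Clock genes changed in both directions, with 8 of 16 higher and 5 lower, or 6 lower over the list alone (camera adjusted p = 0.55). Arntl rose from 23.8 ± 2.04 to 48.9 ± 1.72 CPM (SD, n = 3 each), Cry1 and Ciart rose by 0.81 and 0.72 on the log2 scale, and Per1 fell by 0.70. Of the 4 sex-linked genes tested, all on the Y chromosome, 2 were higher with chemerin-9, Kdm5d by 0.38 and Ddx3y by 0.18 on the log2 scale (camera adjusted p = 0.55). The Ddx3y call was lost with DESeq2, with the GC and length trend removed, and without I/R replicate 3 or any of the chemerin-9 replicates, over adjusted p values of 0.012 to 0.564. KEGG pathways, paired with genes as the authors deposited them, were tested with camera after the data were seen. Of 298 pathways with 10 to 300 tested genes, 6 passed at the preset correlation. With an estimated correlation 0 passed, and the smallest adjusted p was 0.556. In the simulated data that setting recovered 0 of 10 shifted lists, so it does not decide these calls. Ribosome biogenesis was higher, with 42 of 72 genes higher and 8 lower (adjusted p = 3.3e-04), while the ribosome pathway was lower, with 86 of 124 genes lower and 13 higher (adjusted p = 3.3e-04). A rise of non-coding genes, looked for as a pattern, was not found: of 1393 tested non-coding genes 227 rose and 200 fell. Of 781 pseudogenes 70 rose and 155 fell.

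The libraries did not carry the abundant genes of whole kidney. Too little depth was tested with the median count per tested gene, which was 295 in the shallowest library. The tested genes had already passed a filter on low counts, so a low value could hardly come out and the question stays undecided. The value shows only that a gene at the median level would have been counted. Loss of nephron cells with vessel, leukocyte or blood cells filling the sample was tested with their 44 markers pooled. The pooled median reached at most 2.57% of the median of all tested genes. A pooled median can stay low where a single cell type is abundant, so it does not decide this. By cell type, macrophage markers had the highest median, at 4.41 CPM in chemerin-9 replicate 3, against 25.7 CPM for all tested genes. This level argues against any of these types filling the sample. A candidate explanation is that the counts come from a dividing cell population and not from whole kidney. Pooled nephron markers reached at most 8.29% of the median of all tested genes, while cell division genes were at no less than 795% of it. By cell type, podocyte markers were highest, with a median of 8.10 CPM in chemerin-9 replicate 1, against 25.7 CPM for all tested genes. Another candidate is dividing fibroblasts of the organ filling the sample. Fibroblast and matrix genes were at no less than 181% of the median of all tested genes. Matrix-producing cells from elsewhere could show the same, so this level cannot tell it from the explanation before. Fibroblasts of the organ would also need to have replaced most vessel, leukocyte and blood cells, given the low marker levels above. A mix-up of tables or labels stays open too.

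Interferon response genes fell with chemerin-9. Leukocytes present in I/R only are argued against by the 12 tested leukocyte markers, with a median log2 fold change of -0.057 and a median of 2.60 CPM in I/R, against 40.3 CPM for the interferon genes, although Aif1 and Ccl5 fell. A GC or length bias is argued against as the whole cause by a median of -1.91 with that trend removed, where 29 members still fell. A changing share of a few abundant genes is argued against by the 10 most abundant genes of each library, whose share varied too little to shift all other genes by more than 0.016 on the log2 scale. The treatment, a batch effect (0 of the 6 batch values hold libraries of both groups), a mix-up of tables or labels and the unchecked reading of the column names stay open.

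The fall of heat shock genes kept a median of -0.81 with the GC and length trend removed, with all 13 genes still lower, and the share of the 10 most abundant genes could shift all other genes by at most 0.016, so neither is the whole cause. A difference in handling between processing days, if the batch values are real days, may act on such stress genes and cannot be told apart from the treatment, since 0 of the 6 batch values hold libraries of both groups. Hspa8 varied little between the batch values of one group, with an SD of 24.0 around 1948 CPM and of 8.38 around 467 CPM. A mix-up of tables or labels stays open here too.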
